A study of Mus musculus with 32 samples.

How the data were processed

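A set of 3 chromatin marks was profiled by CUT&Tag, which uses an antibody-tethered transposase to release DNA beside a mark, in mouse bone-marrow progenitors kept dividing by an estrogen-dependent HoxB8. Estrogen had been withdrawn for 48 h. The marks were H3K27me3 and H2AK119ub, the products of the Polycomb repressive complexes, and H3K4me1, found at enhancers and around promoters. Each mark had 10 libraries in 4 groups: 2 control libraries (non-targeting guide and empty vector), 3 with an Asxl1 guide and empty vector, 3 with the non-targeting guide and CSF3R T618I, and 2 with both (called double here). A list of peaks from 2 merged IgG libraries served as background. Per the labels, the authors aligned reads with Bowtie2 2.4.1 to mm10 and used deepTools 3.5. The peak caller and its threshold are not given in the sources used here.

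The deposited values are of a kind other than counts or normalised signal: peak positions in bp, with no height, score or read count. Peak widths were multiples of 50 bp and at least 200 bp. Sequencing depth is unknown, so no counting interval or detection floor can be given, and a longer peak list can come from deeper sequencing.

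For each of 21887 protein-coding genes of GRCm38.p6, the coordinates behind mm10, the fraction of a 10 kb window around 1 end of the gene that lay in peaks was computed per library. The gene table used has no strand, so transcription start sites could not be placed. The end with the higher mean coverage over all 30 libraries was taken without regard to genotype, and it was the left end for 67.6% of genes. Such a gene end can be the 3′ end or lie at a neighbour's promoter, and neighbouring genes can share a window. Gene ends with a fraction of at least 0.2 in at least 2 libraries were tested, which left 3714 for H3K27me3, 3223 for H2AK119ub and 2327 for H3K4me1. Distal H3K4me1 regions were peaks merged over libraries, seen in at least 2 libraries and more than 5 kb from every protein-coding gene end, 15995 in all.

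Fractions were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group, moderated variances and 2-sided tests, and p was adjusted by Benjamini-Hochberg within each mark and comparison. A gene end was called higher or lower at an adjusted p under 0.05. The comparisons were Asxl1 guide against control, CSF3R against control, double against CSF3R, double against control, and the interaction of guide and CSF3R. The 14 gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, and p was adjusted over 160 tests. Of these 15 passed, and each of them had adjusted p = 0.986 with an estimated correlation. The lists held Hox cluster genes, developmental regulators, stem and progenitor genes, myeloid transcription factors, primary granule and early neutrophil genes, late neutrophil genes, and monocyte, macrophage and dendritic genes. The others held JAK-STAT target and cytokine signalling genes, cell cycle inhibitors and D/E cyclins, Polycomb and Asxl/Bap1 complex genes, erythroid and megakaryocyte genes, lymphoid genes, mast cell, basophil and eosinophil genes, and ribosomal protein genes. Lists with fewer than 3 tested members in a mark gave no test.

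Covered length, mean peak width and the share of H3K27me3 inside H2AK119ub were compared by exact 2-sided permutation within strata of the other genotype factor, which gives 100 arrangements and a smallest p of 0.01. Overlap between libraries was the Jaccard index of covered bp, with 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

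Groups, comparisons, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each mark and each of the first 3 comparisons, up to 4 genes with the largest increase and up to 4 with the largest decrease past the threshold, leaving out predicted genes (Gm and Rik symbols). It added up to 2 members of each list by p, the 2 highest and 2 lowest by p where no gene passed, and Asxl1, Csf3r, Hoxb8, Hoxa9, Meis1, Cebpe and Myc in every case. For distal regions it took 2 in each direction. The strand-free gene end replaced the intended start-site window, and mean peak width, the whole-gene window, the joint use of a covered-length covariate and leaving out 1 library, the overlap of calls between marks, the agreement of guide effects and the test of distal regions near listed genes were chosen after seeing the data.

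The alternatives were a 2 kb window, any overlap in place of the fraction, no filter, removal of the shortest peaks or of peaks overlapping IgG peaks, covered length as covariate, a block for replicate number, merged peak regions, complete separation of groups without a test, at least 3 libraries per distal region, a 2 kb distance for distal regions, peak number in place of covered length, other overlap measures, and leaving out each library in turn. Where this left 1 library in a group, that library was assumed to vary like the other groups. A peak sharing 1 bp with an IgG peak was removed whole, so wide peaks were lost more often. In H3K27me3 CSF3R replicate 1, 2.36% of the length lay inside IgG peaks, but the removal took covered length from 31.3 to 22.8 Mb. The fit was tested on simulated data: of 100 gene ends shifted by 0.6 in double against CSF3R, 75% were recovered for H3K27me3, 97% for H2AK119ub and 98% for H3K4me1, and of those shifted by 0.3, 6%, 54% and 67%. Residuals were shuffled separately for each gene end, so shifts shared by a whole library were not simulated. The merged IgG list entered no genotype comparison, since it gives 1 list for both of its genotypes.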

Results

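The series pairs a CRISPR truncation of Asxl1, whose protein works with Bap1 to remove ubiquitin from histone H2A, with CSF3R T618I, an activating form of the G-CSF receptor found in chronic neutrophilic leukaemia. Its title concerns the effect of mutant Asxl1 on differentiation in CSF3R-driven disease. H3K27me3, H2AK119ub and H3K4me1 were mapped in mouse HoxB8 progenitors 48 h after estrogen removal, in 4 genotypes per mark: control (n = 2), Asxl1 guide (n = 3), CSF3R (n = 3) and both (double, n = 2). Values are the fraction of a 10 kb window at a gene end that lay in peaks, as mean ± SD over those libraries, and positions are mm10. Peak lists held 6071 to 45373 peaks for H3K27me3, 10866 to 33969 for H2AK119ub and 14479 to 21185 for H3K4me1, and sequencing depth is unknown. Editing of Asxl1 could not be checked with these marks: its gene end had no H3K27me3 or H2AK119ub peak in any library, and H3K4me1 covered at most 0.11 of it, in 4 libraries. The Csf3r gene end also had no H3K27me3 or H2AK119ub peak in any library.

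H3K27me3 peaks were narrower in cells with the Asxl1 guide, with and without CSF3R T618I. Mean width was 1576 ± 18.7 bp (SD, n = 2) in control and 973 ± 194 bp (n = 3) with the guide. With CSF3R T618I it was 1904 ± 132 bp (n = 3), and in double cells 950 ± 260 bp (n = 2). Peaks longer than 5 kb held 33.3% of the H3K27me3 length in control, 13.9% with the guide, 44.0% with CSF3R and 16.1% in double cells. The average guide effect on log2 mean width was -0.87, a ratio of 0.547, with an exact permutation p of 0.01, the smallest that 100 arrangements can give. The guide effect on width was -0.16 for H2AK119ub (exact permutation p = 0.04), which no longer passed without any 1 library other than CSF3R replicate 3 or double replicate 1 (-0.18 to -0.07), with median width (exact permutation p = 0.08) or with covered length in the fit (exact permutation p = 0.14). It was -0.13 for H3K4me1 (exact permutation p = 0.06), and the CSF3R effect on H3K27me3 width was 0.11 (exact permutation p = 0.48). Width was chosen as a measure after seeing the data.

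Total H3K27me3 length was 19.3 ± 4.82 Mb in control, 23.4 ± 25.9 Mb with the Asxl1 guide, 35.9 ± 5.62 Mb with CSF3R and 16.7 ± 3.55 Mb in double cells. The spread with the guide came from Asxl1 replicate 2, which covered 53.0 Mb against 4.73 and 12.4 Mb in the other replicates, and only 32.5% of its length lay in gene-end windows. H2AK119ub covered 20.6 ± 0.876, 13.9 ± 2.49, 25.2 ± 5.57 and 30.9 ± 11.7 Mb in the same order, and H3K4me1 37.3 ± 0.917, 33.3 ± 5.99, 41.8 ± 5.08 and 36.7 ± 9.55 Mb. The average CSF3R effect on log2 covered length was 0.69 for H2AK119ub, with an exact permutation p of 0.04. It no longer passed without any 1 library other than CSF3R replicate 1, with effects of 0.49 to 0.89. Guide effects were -0.74 for H3K27me3 (exact permutation p = 0.30), -0.16 for H2AK119ub (exact permutation p = 0.54) and -0.19 for H3K4me1 (exact permutation p = 0.26). The other CSF3R effects were 0.54 for H3K27me3 (exact permutation p = 0.46) and 0.15 for H3K4me1 (exact permutation p = 0.35). Without Asxl1 replicate 2 the H3K27me3 effects became -1.21 for the guide and 1.01 for CSF3R, each with an exact permutation p of 0.0167, the smallest possible there.

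**Figure D1:**
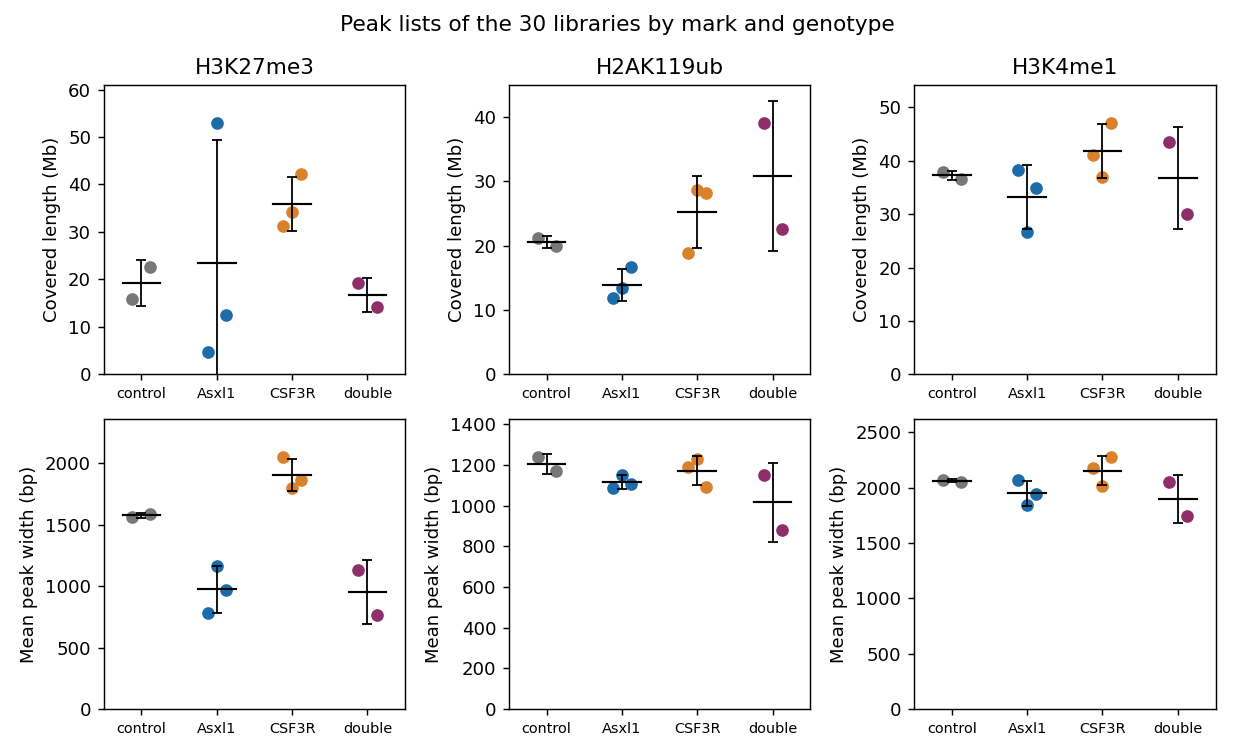
Covered length in Mb (top) and mean peak width in bp (bottom) for each mark and genotype, with dots for libraries, lines for means and bars for SD; the SD bar of the H3K27me3 covered length with the Asxl1 guide runs below the axis. Mean H3K27me3 width is 973 bp with the guide and 950 bp in double cells, against 1576 bp in control and 1904 bp with CSF3R.

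Averaged over all pairs, libraries of 1 genotype shared more of their covered bp than libraries of different genotypes in each mark. The mean Jaccard index within and between genotypes was 0.43 and 0.33 for H3K27me3 (permutation p = 0.0129), 0.46 and 0.36 for H2AK119ub (permutation p = 0.00034) and 0.68 and 0.57 for H3K4me1 (permutation p = 0.00029). For H3K4me1 the mean overlap with control was 0.67 for guide-only cells, 0.60 for CSF3R cells and 0.49 for double cells. For H3K27me3 the 3 CSF3R libraries overlapped each other by 0.63. The 3 H3K27me3 guide libraries went the other way, with 0.21 among themselves against 0.31 with control, 0.28 with double and 0.27 with CSF3R. Their unequal covered lengths of 4.73, 53.0 and 12.4 Mb limit this index. Of the shorter list in each pair of them, 88.3 to 99.5% of the length lay inside the longer, so the low index does not show unlike positions.

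The first H3K27me3 comparison asked what the Asxl1 guide does in cells without CSF3R T618I. Gene ends of Hox cluster genes, the homeobox genes silenced by Polycomb as progenitors mature, had a median difference of -0.29 from control, against -0.05 for all tested gene ends. Developmental regulators, the transcription factors that pattern embryonic tissues, had a median difference of -0.23. The guide libraries spread widely: their Hox means ran from 0.06 to 0.65, against 0.55 to 0.63 in control, and their developmental means from 0.22 to 0.74, against 0.68 to 0.73. So 1 of the 3 lay above both controls in each list. Hoxa9, a driver of progenitor self-renewal, was covered over 1 ± 0 of its window in control (n = 2) and 0.37 ± 0.37 with the guide (n = 3; adjusted p = 0.677). The cell's own Hoxb8 gene, as distinct from the estrogen-dependent HoxB8 that kept these cells dividing, had 0.61 ± 0.07 and 0.22 ± 0.33 (adjusted p = 0.772). Meis1, a Hox cofactor, had 0.21 ± 0.02 and 0.15 ± 0.03 (adjusted p = 0.934). Sall3, a zinc-finger developmental regulator, had 0.87 ± 0.07 and 0.31 ± 0.07 (adjusted p = 0.244), and Sbf2 0.62 ± 0.06 and 0.12 ± 0.14 (adjusted p = 0.677). The ephrin receptor gene Epha7 had 0.00 ± 0.00 and 0.26 ± 0.11 (adjusted p = 0.685), and Mreg 0.01 ± 0.02 and 0.22 ± 0.08 (adjusted p = 0.772). No gene end of 3714 passed in limma, with 235 at an unadjusted p under 0.05, and this included 0 of 36 Hox and 0 of 105 developmental genes, also when adjusted over the list alone. Camera called both lists lower relative to other genes, with adjusted p = 1.22e-07 for Hox and 3.25e-10 for developmental regulators, each with adjusted p = 0.986 with an estimated correlation. Without peaks overlapping IgG peaks the Hox call was lost (adjusted p = 0.354). Without Asxl1 replicate 2, 1 gene end was higher and 827 were lower.

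CSF3R T618I was compared with control to see which gene ends it changes on its own. Irf8, the transcription factor that directs progenitors to monocytes and dendritic cells, went from 0.00 ± 0.00 in control (n = 2) to 0.43 ± 0.07 with CSF3R (n = 3; adjusted p = 0.021). Rxra, a nuclear receptor of myeloid cells, went from 0.16 ± 0.07 to 0.70 ± 0.16 (adjusted p = 0.0236). Ccnd2, a D-type cyclin, rose from 0.14 ± 0.16 to 0.68 ± 0.12, and Ebf1, a B-cell factor, from 0.16 ± 0.07 to 0.78 ± 0.05. Hmga2, a chromatin protein of immature cells, rose from 0.01 ± 0.01 to 0.43 ± 0.09. The largest increases were at Adgrg5 (0.17 ± 0.00 to 0.93 ± 0.06), Rnf220 (0.05 ± 0.07 to 0.75 ± 0.01), Cds1 (0.06 ± 0.08 to 0.74 ± 0.07) and Fam222a (0.13 ± 0.11 to 0.81 ± 0.00). Of 9 myeloid transcription factors 2 rose, Irf8 and Rxra, 6 when adjusted over the list alone. Camera called the list higher (adjusted p = 0.021; adjusted p = 0.986 with an estimated correlation). Developmental regulators were called lower relative to other genes (adjusted p = 0.000723; adjusted p = 0.986 with an estimated correlation), although their median difference was 0.09, below the 0.15 of all gene ends. Of these genes 2 of 105, Nkx6-2 and Six4, rose (2 adjusted over the list alone). Hoxa9 had 0.90 ± 0.11, Hoxb8 0.86 ± 0.02 and Meis1 0.21 ± 0.01 with CSF3R, and none of these passed (adjusted p = 0.724, 0.315 and 1).

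In this comparison 106 gene ends rose and 0 fell in limma, with 893 at an unadjusted p under 0.05. The count fell to 0 without control replicate 1, control replicate 2, CSF3R replicate 2 or CSF3R replicate 3 (328, 651, 647 and 485 at an unadjusted p under 0.05). It was 12 without Asxl1 replicate 3, 23 without double replicate 1, 22 without double replicate 2, 256 without Asxl1 replicate 1 and 1137 higher with 2 lower without Asxl1 replicate 2. None (0) of the 11 named genes kept its call in all of these fits. The call of the myeloid list was lost without control replicate 2 (adjusted p = 0.115), Asxl1 replicate 1 (0.0529) or Asxl1 replicate 2 (0.0519), and with the whole-gene window (0.614). With the whole-gene window or merged regions no feature was called, as the closing section lists.

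Double against CSF3R, which compares CSF3R-mutant cells with and without the Asxl1 guide, gave the most H3K27me3 calls, nearly all of them losses. Other differences between these cells, and covered length, go with the guide in this comparison. Hoxa9 fell from 0.90 ± 0.11 with CSF3R (n = 3) to 0.19 ± 0.01 in double cells (n = 2; adjusted p = 0.0255), and Hoxb8 from 0.86 ± 0.02 to 0.37 ± 0.04 (adjusted p = 0.0456). Gata2, a stem and mast cell transcription factor, fell from 0.70 ± 0.06 to 0.06 ± 0.09 (adjusted p = 0.00988). Irf8 fell from 0.43 ± 0.07 to 0.00 ± 0.00 (adjusted p = 0.011) and Rxra from 0.70 ± 0.16 to 0.00 ± 0.00 (adjusted p = 0.00988). Among cell cycle inhibitors, Cdkn2a, which encodes p16 and p19Arf, fell from 0.71 ± 0.00 to 0.22 ± 0.07, and Cdkn1c, which encodes p57, from 0.94 ± 0.10 to 0.17 ± 0.22. Of 36 Hox genes 16 fell, 26 adjusted over the list alone, including Hoxc8 (0.79 ± 0.03 to 0.14 ± 0.09) and Hoxd4 (0.75 ± 0.09 to 0.04 ± 0.02). Hox genes lie in clusters where windows of neighbours can overlap, so these members are not independent. This Hox count was 6 without either control library, 9 without Asxl1 replicate 3, 3 without CSF3R replicate 1, 2 without CSF3R replicate 2, 28 without Asxl1 replicate 1 and 36 without Asxl1 replicate 2. It was 0 in limma without CSF3R replicate 3, double replicate 1 or double replicate 2, where no gene end passed (1078, 1204 and 798 of all gene ends at an unadjusted p under 0.05). The directions at Hoxa9, Hoxb8, Cdkn1c and Kif1c turned positive, at 0.08, 0.13, 0.06 and 0.06, without peaks overlapping IgG peaks. That setting removes whole peaks, wide ones more often, so these turns can follow from peak width and do not show background.

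Other lists lost H3K27me3 in double cells at part of their gene ends, as tested gene ends did in general. Camera called none of these lists in this comparison. Developmental regulators fell at 31 of 105 (45 adjusted over the list alone), among them Nkx6-2 (0.48 ± 0.07 to 0.00 ± 0.00) and Six4 (0.49 ± 0.07 to 0.00 ± 0.00). Stem and progenitor genes fell at 3 of 16 (3 adjusted over the list alone), myeloid transcription factors at 4 of 9 (4) and cell cycle genes at 3 of 8 (3). Polycomb and Asxl/Bap1 complex genes fell at 3 of 7 (3), including Phf19 (0.34 ± 0.04 to 0.02 ± 0.03) and Rybp (0.36 ± 0.08 to 0.07 ± 0.02), partners of Polycomb complexes. Lymphoid genes fell at 3 of 9 (6 adjusted over the list alone). The T-cell factor Tcf7 went from 0.57 ± 0.13 to 0.12 ± 0.05 and the B-cell factor Pax5 from 1 ± 0 to 0.37 ± 0.12. JAK-STAT and cytokine genes fell at 2 of 7 (3 adjusted over the list alone): Il6st, the shared IL-6 receptor chain, from 0.55 ± 0.15 to 0.03 ± 0.01, and the erythropoietin receptor gene Epor, from 0.35 ± 0.07 to 0.00 ± 0.00. Epor was also the 1 of 7 erythroid and megakaryocyte genes that fell (1 adjusted over the list alone). Il13, a type 2 cytokine gene, fell from 0.30 ± 0.15 to 0.00 ± 0.00 and the neutrophil protease gene Mmp9 from 0.53 ± 0.00 to 0.19 ± 0.05. Irf8 was the 1 of 8 monocyte genes that fell (1 adjusted over the list alone). Of 3 ribosomal protein genes 0 passed in limma, also when adjusted over the list alone. The largest decreases were at Kif1c (0.95 ± 0.08 to 0.13 ± 0.06) and Parp12 (0.80 ± 0.14 to 0.00 ± 0.00). Espn (0.95 ± 0.09 to 0.14 ± 0.02) and its neighbour Tnfrsf25 (0.94 ± 0.10 to 0.14 ± 0.02), which share most of a window, came with them.

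H3K27me3 rose in double cells at few gene ends. Zfp516, a zinc-finger gene, went from 0.00 ± 0.00 with CSF3R (n = 3) to 0.73 ± 0.26 in double cells (n = 2; adjusted p = 0.00988), and Itgb3, the platelet integrin beta 3 gene, from 0.00 ± 0.00 to 0.33 ± 0.18 (adjusted p = 0.0286). Plxnc1, a semaphorin receptor gene, rose from 0.10 ± 0.01 to 0.41 ± 0.00 and Epha7 from 0.05 ± 0.04 to 0.32 ± 0.00. In all, 6 gene ends rose and 846 fell, of 3714 tested. The share that fell was below this among stem and progenitor, erythroid and megakaryocyte, monocyte and ribosomal protein genes. It was above it in the other lists counted. Camera called Hox genes lower relative to other genes (median -0.43 against -0.24 for all; adjusted p = 0.0163; adjusted p = 0.986 with an estimated correlation). This was lost without CSF3R replicate 1 (adjusted p = 0.325), without double replicate 1 (0.0952), with a 2 kb window (0.205) and without peaks overlapping IgG peaks (0.274, turned upward relative to other genes). Meis1 had 0.21 ± 0.01 with CSF3R and 0.21 ± 0.03 in double cells (adjusted p = 0.933).

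These counts leaned on single libraries. No gene end passed without CSF3R replicate 3, double replicate 1 or double replicate 2 (1078, 1204 and 798 at an unadjusted p under 0.05). Gene ends that fell numbered 399 without either control library, 375 without Asxl1 replicate 3, 340 without CSF3R replicate 1, 124 without CSF3R replicate 2, 1587 without Asxl1 replicate 1 and 2384 without Asxl1 replicate 2. None (0) of the 27 named genes kept its call in all 10 of these fits. With covered length in the fit 1157 fell, and with Asxl1 replicate 2 also left out 564 fell, while 484 of the 852 called gene ends kept their call.

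Double cells differed from control by H3K27me3 at 1 gene end that passed, Rnf220 (0.05 ± 0.07 in control, n = 2, and 0.68 ± 0.09 in double cells, n = 2; adjusted p = 0.048), named here after its values were seen. Hoxa9 had 1 ± 0 and 0.19 ± 0.01 (adjusted p = 0.301) and Hoxb8 0.61 ± 0.07 and 0.37 ± 0.04 (adjusted p = 0.714). Hox genes (median -0.22, adjusted p = 0.000723) and developmental regulators (median -0.22, adjusted p = 2.8e-06) were called lower relative to other genes, each with adjusted p = 0.986 with an estimated correlation, and with 0 members passing, also when adjusted over the list alone. Both list calls were lost without peaks overlapping IgG peaks (0.561 and 0.274). Without Asxl1 replicate 2, 48 gene ends were higher and 241 lower, without Asxl1 replicate 1, 2 and 3, and without any 1 of the other libraries none passed. The interaction, which asks whether the guide acts differently with CSF3R T618I, gave 0 gene ends in limma (451 at an unadjusted p under 0.05), and 0 in each fit without 1 library. It gave 91 with covered length in the fit, 227 with any overlap, 52 with no filter and 12 without peaks overlapping IgG peaks. Developmental regulators were called higher relative to other genes in the interaction (adjusted p = 0.0016; adjusted p = 0.986 with an estimated correlation), with a median of -0.10 and a mean of -0.13, both below 0, against a median of -0.18 for all gene ends. That call was lost without Asxl1 replicate 1 (0.425) or double replicate 1 (0.0883).

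Asxl1 takes part in removing H2AK119ub, and the guide alone changed this mark mostly downward at the gene ends. Mid1, an X-linked ubiquitin ligase gene, fell from 0.997 ± 0.004 in control (n = 2) to 0.32 ± 0.02 with the guide (n = 3; adjusted p = 0.0013), and Kif19a from 0.78 ± 0.13 to 0.12 ± 0.07 (adjusted p = 0.0144). The ectonucleotidase gene Entpd2 fell from 0.78 ± 0.11 to 0.13 ± 0.02 (adjusted p = 0.0111) and Ccdc9b from 0.66 ± 0.06 to 0.02 ± 0.02 (adjusted p = 0.044). The increases included developmental regulators: En1 from 0.26 ± 0.16 to 0.82 ± 0.07 (adjusted p = 0.0127) and Pax9 from 0.21 ± 0.04 to 0.60 ± 0.07 (adjusted p = 0.0124). The Hedgehog effector gene Gli2 rose from 0.06 ± 0.05 to 0.40 ± 0.09 and Lmx1a from 0.00 ± 0.00 to 0.32 ± 0.13. Gata2 fell from 0.95 ± 0.08 to 0.64 ± 0.07 and the retinoic acid receptor gene Rara from 0.80 ± 0.11 to 0.34 ± 0.13. Fos, an AP-1 gene, fell from 0.28 ± 0.02 to 0.05 ± 0.08 and Cdkn2b, which encodes p15, from 0.27 ± 0.06 to 0.08 ± 0.01. Without peaks overlapping IgG peaks, which removes whole peaks, the directions at Gata2 and Rara turned positive, at 0.22 and 0.16.

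Among the lists, 2 of 91 developmental regulators rose and 6 fell (2 and 6 adjusted over the list alone), and 2 of 19 myeloid transcription factors fell (5 adjusted over the list alone). Further, 1 of 22 stem and progenitor genes, 1 of 9 cell cycle genes and 1 of 3 mast cell genes fell (1, 1 and 1 adjusted over the list alone). No list was called by camera in this comparison. Hoxa9 (0.66 ± 0.00 and 0.60 ± 0.07, adjusted p = 0.659), Hoxb8 (0.48 ± 0.11 and 0.19 ± 0.09, adjusted p = 0.114), Meis1 (0.19 ± 0.00 and 0.19 ± 0.01, adjusted p = 0.961) and Myc (0.14 ± 0.04 and 0.13 ± 0.05, adjusted p = 0.945) did not pass. Of 3223 gene ends 17 rose and 260 fell. The counts higher and lower were 0 and 13 without control replicate 1, 0 and 16 without control replicate 2, 0 and 11 without Asxl1 replicate 1, 5 and 92 without Asxl1 replicate 2 and 6 and 150 without Asxl1 replicate 3. Only 1 of the 13 named genes, Mid1, kept its call in all 10 such fits. With covered length in the fit 6 rose and 15 fell, and 18 of the 277 calls were kept. Mid1 lies on the X chromosome, which held 63, 71 and 98 H2AK119ub peaks with the guide and 261 and 249 in control. All peaks numbered 10866, 11623 and 15063 against 17116 and 17030. With CSF3R the X held 182, 357 and 355 of 15788, 23338 and 25860 peaks, and in double cells 200 and 158 of 33969 and 25715. Each library with the guide thus had a smaller share of its H2AK119ub peaks on the X than each library without it. These values argue against a fall limited to Mid1 on the X. Whether Mid1 fell beyond this wider difference was not tested.

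With CSF3R T618I alone, H2AK119ub changed at few gene ends. Etv3l, an ETS factor gene, rose from 0.14 ± 0.05 in control (n = 2) to 0.74 ± 0.08 (n = 3; adjusted p = 0.00509). Hif1an, which encodes an oxygen-sensing hydroxylase that restrains HIF1, rose from 0.28 ± 0.18 to 0.83 ± 0.03 (adjusted p = 0.0125). Increases were also called at Ppfia1, from 0.17 ± 0.23 to 0.74 ± 0.11 (adjusted p = 0.0422), and the mucin gene Muc4, from 0.32 ± 0.13 to 0.86 ± 0.07 (adjusted p = 0.0469). Foxo1, a transcription factor gene restrained by growth factor signalling, fell from 0.58 ± 0.13 to 0.10 ± 0.11 (adjusted p = 0.0469), the 1 gene end of 3223 that did, while 17 rose. Muc4 turned to -0.09 without peaks overlapping IgG peaks. Hox genes (median -0.06, adjusted p = 0.00358) and developmental regulators (median -0.02, adjusted p = 0.0023) were called lower relative to other genes, each with adjusted p = 0.986 with an estimated correlation; 0 members passed, also when adjusted over the list alone. The Hox call was lost without control replicate 1 (0.107) or CSF3R replicate 3 (0.0502) and with a 2 kb window (0.0772), where its median was 0.0014. The developmental call was lost without CSF3R replicate 3 (0.0527) and without peaks overlapping IgG peaks (0.119). Hoxa9, Hoxb8, Meis1 and Myc had 0.51 ± 0.13, 0.41 ± 0.14, 0.20 ± 0.01 and 0.26 ± 0.13 with CSF3R and did not pass.

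Counts higher and lower in that comparison were 3 and 0 without control replicate 1, 0 without control replicate 2 (334 at an unadjusted p under 0.05 in limma) and 6 and 0 without Asxl1 replicate 1. They were 5 and 0 without Asxl1 replicate 2 or Asxl1 replicate 3, and 80 and 1 without CSF3R replicate 1. They were 4 and 0 without CSF3R replicate 2 or CSF3R replicate 3, and 36 and 5 without either double library. None (0) of the 5 named genes, Etv3l, Hif1an, Ppfia1, Muc4 and Foxo1, kept its call in all 10 fits.

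In CSF3R-mutant cells the guide moved H2AK119ub in both directions. Zfp516 rose from 0.02 ± 0.03 with CSF3R (n = 3) to 0.69 ± 0.08 in double cells (n = 2; adjusted p = 0.000401) and Itgb3 from 0.16 ± 0.07 to 0.80 ± 0.07 (adjusted p = 0.000662), and both also gained H3K27me3. Grhl3, an epithelial transcription factor gene, rose from 0.09 ± 0.07 to 0.67 ± 0.00 and the aquaporin gene Aqp12 from 0.05 ± 0.03 to 0.63 ± 0.11. Of 22 stem and progenitor genes 3 rose (3 adjusted over the list alone), including Runx1, a master factor of blood formation, from 0.41 ± 0.05 to 0.79 ± 0.28, and the angiopoietin gene Angpt1 from 0.04 ± 0.01 to 0.39 ± 0.26. Some signalling genes went the other way. Pim3, a kinase gene induced by STAT proteins, fell from 0.89 ± 0.11 to 0.19 ± 0.10 (adjusted p = 0.00411). Stat5b and Stat5a, which encode cytokine-activated transcription factors and share most of a window, fell from 0.26 ± 0.02 to 0.00 ± 0.00 and from 0.25 ± 0.00 to 0.00 ± 0.00.

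Of 15 JAK-STAT and cytokine genes 1 rose and 3 fell (3 and 3 adjusted over the list alone), and of 19 myeloid transcription factors 1 rose and 3 fell (2 and 3). The medians of these lists were above 0 (0.01 and 0.02) and their means below it (-0.04 and -0.02). Pcgf2, a Polycomb component gene, fell from 0.25 ± 0.09 to 0.01 ± 0.01, the 1 of 5 of its list (3 adjusted over the list alone), and Rps15, a ribosomal protein gene, from 0.36 ± 0.01 to 0.07 ± 0.02. The largest other decreases were at Crip1, from 0.93 ± 0.07 to 0.28 ± 0.22, Tmem200b, from 0.65 ± 0.09 to 0.05 ± 0.00, and Clba1, from 0.71 ± 0.32 to 0.13 ± 0.14. Pax9 rose again, from 0.13 ± 0.04 to 0.54 ± 0.14, and Tbx10 fell from 0.38 ± 0.06 to 0.11 ± 0.02. Of 91 developmental regulators 3 rose and 2 fell (1 and 2 adjusted over the list alone). Hox genes were called higher relative to other genes (median 0.08, adjusted p = 0.015; adjusted p = 0.986 with an estimated correlation), with 0 of 27 passing, also adjusted over the list alone. This was lost without CSF3R replicate 1 (0.079), CSF3R replicate 3 (0.074) or double replicate 1 (0.0634) and without peaks overlapping IgG peaks (0.207). Hoxa9 had 0.51 ± 0.13 and 0.66 ± 0.02 (adjusted p = 0.209), and Hoxb8 0.41 ± 0.14 and 0.64 ± 0.21 (adjusted p = 0.198). Meis1 had 0.20 ± 0.01 and 0.20 ± 0.04 (adjusted p = 0.943) and Myc 0.26 ± 0.13 and 0.41 ± 0.02 (adjusted p = 0.229).

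Across all gene ends 122 rose and 213 fell, and 7 of the 16 named genes kept their call in every fit that left out 1 library: Itgb3, Grhl3, Pax9, Pim3, Stat5a, Stat5b and Tmem200b. Another 2, Zfp516 and Aqp12, had too little coverage to be tested without either double library. The counts higher and lower changed to 78 and 109 without Asxl1 replicate 1, 78 and 111 without Asxl1 replicate 2, 84 and 115 without Asxl1 replicate 3, and 99 and 368 without CSF3R replicate 1. They were 77 and 69 without CSF3R replicate 2, 34 and 46 without CSF3R replicate 3, 14 and 150 without double replicate 1, and 116 and 33 without double replicate 2. With covered length in the fit 148 rose and 537 fell. Against control, double cells had 164 gene ends higher and 64 lower, with 4 of 22 stem and progenitor genes higher (4 adjusted over the list alone). Myc, a growth regulator, had 0.14 ± 0.04 in control (n = 2) and 0.41 ± 0.02 in double cells (n = 2; adjusted p = 0.0746). Those counts were 38 and 24 without control replicate 1, 34 and 24 without control replicate 2, 181 and 99 without CSF3R replicate 1, 41 and 68 without double replicate 1 and 204 and 37 without double replicate 2. Runx1 was among the 4, with 0.10 ± 0.01 in control and 0.79 ± 0.28 in double cells.

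The guide effect on H2AK119ub differed with CSF3R status at 8 gene ends, of which 7 had a positive interaction and 1, Selenoo, a negative one. Zfp516 was covered over 0.01 ± 0.01 in control, 0.03 ± 0.03 with the guide, 0.02 ± 0.03 with CSF3R and 0.69 ± 0.08 in double cells (interaction 0.66, adjusted p = 0.0146). Snai3, a Snail-family repressor gene, named with Selenoo and Xirp1 after their values were seen, had 0.57 ± 0.04, 0.06 ± 0.02, 0.50 ± 0.02 and 0.62 ± 0.10 (interaction 0.62, adjusted p = 0.0146). Xirp1 had 0.59 ± 0.05, 0.04 ± 0.05, 0.41 ± 0.08 and 0.44 ± 0.06 (adjusted p = 0.0439), and Selenoo 0.09 ± 0.01, 0.00 ± 0.00, 0.60 ± 0.05 and 0.08 ± 0.04 (adjusted p = 0.0496). Hox genes were called higher in the interaction (median 0.17, adjusted p = 0.0293; adjusted p = 0.986 with an estimated correlation), with 0 of 27 members passing and 4 adjusted over the list alone. The Hox call was lost without control replicate 1 (0.209), CSF3R replicate 1 (0.121), CSF3R replicate 3 (0.155) or double replicate 1 (0.0858), with covered length in the fit (0.334) and in 3 other settings. The count of 8 fell to 0 in limma (351 at an unadjusted p under 0.05 in the full fit) without either control library, any 1 of the 3 Asxl1 libraries or double replicate 1. It was 4 without CSF3R replicate 1, 2 without CSF3R replicate 2 and 56 without double replicate 2.

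H3K27me3 and H2AK119ub often lie together. In control 42.0 ± 7.53% of the H3K27me3 length lay inside H2AK119ub peaks of the same replicate number, against 42.5 ± 23.1% with the guide, 32.5 ± 4.57% with CSF3R and 53.5 ± 7.60% in double cells. The average guide effect was 10.7 percentage points (exact permutation p = 0.29). Without Asxl1 replicate 2, whose share was 16.4% against 60.0% and 51.2% in the other Asxl1 replicates, it was 17.3 points (exact permutation p = 0.0167, the smallest possible there). The share depends on the covered length of both marks. Asxl1 replicate 2 had 53.0 Mb of H3K27me3 against 13.4 Mb of H2AK119ub, so most of its H3K27me3 could not lie inside. The guide effect on the share was not tested apart from covered length.

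With the Asxl1 guide alone, no H3K4me1 value passed at a gene end. Tal2, a helix-loop-helix factor gene first found in T-cell leukaemia, had 0.55 ± 0.00 in control (n = 2) and 0.16 ± 0.07 with the guide (n = 3; adjusted p = 0.0535), and the protease gene Tmprss3 0.41 ± 0.04 and 0.08 ± 0.05 (adjusted p = 0.0535). Coq10b, a coenzyme Q gene, had 0.04 ± 0.01 and 0.25 ± 0.02 (adjusted p = 0.0685), and Isca1, an iron-sulfur assembly gene, 0.13 ± 0.01 and 0.27 ± 0.00 (adjusted p = 0.146). Cebpe, the factor that drives granule formation in neutrophils, had 0.43 ± 0.05 and 0.36 ± 0.05 (adjusted p = 0.934) and Csf3r 0.41 ± 0.02 and 0.40 ± 0.05 (adjusted p = 1). No gene end of 2327 passed in limma, with 205 at an unadjusted p under 0.05, and no list was called.

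With CSF3R T618I alone H3K4me1 rose at 189 gene ends, 5 of them of late neutrophil genes. Cd177, a surface protein gene of neutrophils, went from 0.01 ± 0.02 in control (n = 2) to 0.88 ± 0.11 with CSF3R (n = 3; adjusted p = 9.22e-05), and Retnlg, a secreted protein gene of mature neutrophils, from 0.11 ± 0.02 to 0.56 ± 0.02 (adjusted p = 0.000564). Of 35 late neutrophil genes 5 rose and 0 fell (7 and 1 adjusted over the list alone). These were Cd177, Retnlg, the formyl peptide receptor genes Fpr1 and Fpr2, and Ifitm6, and camera did not call the list (adjusted p = 0.153). Saa1, an acute-phase gene, rose from 0.02 ± 0.03 to 0.68 ± 0.14, and Ambp, which encodes a plasma glycoprotein, from 0.00 ± 0.00 to 0.68 ± 0.02 (adjusted p = 1.6e-05). Usp32, a deubiquitinase gene, rose from 0.18 ± 0.03 to 0.87 ± 0.10. Of 13 monocyte, macrophage and dendritic genes 2 rose and 2 fell (3 and 2 adjusted over the list alone). Cd74, the class II invariant chain gene, went from 0.02 ± 0.02 to 0.35 ± 0.07 and Csf1r, the macrophage growth factor receptor gene, from 0.33 ± 0.11 to 0.03 ± 0.03.

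The B-cell progenitor genes Vpreb1 (0.57 ± 0.02 to 0.36 ± 0.01) and Igll1 (1 ± 0 to 0.72 ± 0.11) fell, which made 2 of 4 lymphoid genes (2 adjusted over the list alone). Fosl1, an AP-1 gene, rose from 0.07 ± 0.02 to 0.28 ± 0.05, the 1 of 18 myeloid transcription factors (1 adjusted over the list alone). E2f1, an S-phase factor gene, rose from 0.11 ± 0.05 to 0.38 ± 0.03, the 1 of 6 cell cycle genes (1 adjusted over the list alone). The largest decreases were at Atp8a2 (0.59 ± 0.12 to 0.13 ± 0.09), the apelin receptor gene Aplnr (0.41 ± 0.02 to 0.00 ± 0.00), the integrin gene Itgb5 (0.80 ± 0.11 to 0.43 ± 0.10) and Fam83a (0.54 ± 0.06 to 0.18 ± 0.07). Csf3r had 0.64 ± 0.13 with CSF3R (adjusted p = 0.118) and Cebpe 0.47 ± 0.09 (adjusted p = 0.786). Of 9 primary granule and early neutrophil genes none (0) passed in limma in the first 3 comparisons (2 lower with the guide alone and 2 higher in this one when adjusted over the list alone). In all 189 gene ends rose and 43 fell, and 7 of 15 named genes kept their call in every fit leaving out 1 library: Ambp, Cd177, Cd74, Fam83a, Retnlg, Saa1 and Usp32. Csf1r could not be tested without either control library. Counts were 63 and 7 without control replicate 1, 64 and 5 without control replicate 2, 168 and 26 without CSF3R replicate 2 and 106 and 46 without CSF3R replicate 3.

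In double cells H3K4me1 was lower than with CSF3R at part of the same neutrophil list. Cd177 fell from 0.88 ± 0.11 with CSF3R (n = 3) to 0.15 ± 0.07 in double cells (n = 2; adjusted p = 0.000213) and Retnlg from 0.56 ± 0.02 to 0.23 ± 0.10 (adjusted p = 0.00296). With Cxcr2, a neutrophil chemokine receptor gene, S100a9, and the granule protein genes Camp and Ltf, 6 of 35 late neutrophil genes fell (6 adjusted over the list alone; camera adjusted p = 0.272). Of the late neutrophil genes that rose with CSF3R, Cd177 and Retnlg were among these 6, and Fpr1, Fpr2 and Ifitm6 were not. Gene ends in general also fell more often than they rose here. Of 8 mast cell, basophil and eosinophil genes 2 rose. Cma1, the mast cell chymase gene, rose from 0.02 ± 0.04 to 0.42 ± 0.02 (adjusted p = 0.000239) and Il13 from 0.06 ± 0.05 to 0.25 ± 0.00 (adjusted p = 0.0124), and 2 did when adjusted over the list alone. Camera called that list higher (median 0.04 against -0.06 for all; adjusted p = 0.00582; adjusted p = 0.986 with an estimated correlation). The call was lost without double replicate 1 (0.797, median -0.06) and without double replicate 2 (0.214).

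Ccr4, a chemokine receptor gene of T helper 2 cells, rose from 0.16 ± 0.11 to 0.87 ± 0.02 (adjusted p = 0.000213), and Mrtfb, a coactivator gene of serum response factor, from 0.17 ± 0.12 to 0.72 ± 0.10. Ano2, a chloride channel gene, rose from 0.00 ± 0.00 to 0.54 ± 0.10 and Muc1 from 0.27 ± 0.14 to 0.77 ± 0.33. Lgals3, the galectin 3 gene, rose from 0.11 ± 0.04 to 0.46 ± 0.17 and Ctla4, a T-cell checkpoint gene, from 0.07 ± 0.03 to 0.25 ± 0.05. The lipid droplet gene Plin3 fell from 0.69 ± 0.04 to 0.00 ± 0.00, and Naxd and Cars2, which share most of a window, from 0.63 ± 0.02 to 0.04 ± 0.06 and from 0.62 ± 0.02 to 0.05 ± 0.07. Among transcription factors Nr4a1 fell from 0.50 ± 0.14 to 0.17 ± 0.00 and Fosl1 from 0.28 ± 0.05 to 0.10 ± 0.02 (2 of 18 myeloid factors; 2 adjusted over the list alone). E2f1 fell from 0.38 ± 0.03 to 0.07 ± 0.04 and the cyclin D3 gene Ccnd3 from 0.59 ± 0.10 to 0.29 ± 0.02 (2 of 6 cell cycle genes; 2 adjusted over the list alone). The cytokine signalling genes Il4ra (0.56 ± 0.07 to 0.23 ± 0.00) and Socs3 (0.72 ± 0.04 to 0.56 ± 0.02) fell, so that 1 of 16 genes of their list rose and 2 fell (1 and 3 adjusted over the list alone). Of 13 monocyte genes 1, Lgals3, rose and 1, Cd68, fell, from 0.29 ± 0.02 to 0.13 ± 0.08 (1 and 1 adjusted over the list alone). Csf3r had 0.45 ± 0.13 (adjusted p = 0.163) and Cebpe 0.61 ± 0.02 (adjusted p = 0.153) in double cells.

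In this comparison 56 gene ends rose and 251 fell, and 7 of 20 named genes kept their call in every fit leaving out 1 library: Cd177, Retnlg, Ccr4, Mrtfb, Plin3, Naxd and Cars2. Another 5, Cma1, Il13, Ano2, Lgals3 and Ctla4, could not be tested without either double library. Counts were 57 and 121 without CSF3R replicate 3, 12 and 152 without double replicate 1 and 14 and 48 without double replicate 2. Against control, double cells had 211 gene ends higher and 262 lower, 81 and 90 without control replicate 1, 86 and 92 without control replicate 2, 73 and 162 without double replicate 1 and 142 and 109 without double replicate 2. Of 9 primary granule genes 1, Prtn3, the proteinase 3 gene, rose and 1, Fcnb, the ficolin B gene, fell (2 and 2 adjusted over the list alone), both named after their values were seen. Of 35 late neutrophil genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), and 1 of 6 ribosomal protein genes rose (1 adjusted over the list alone).

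**Figure D2:**
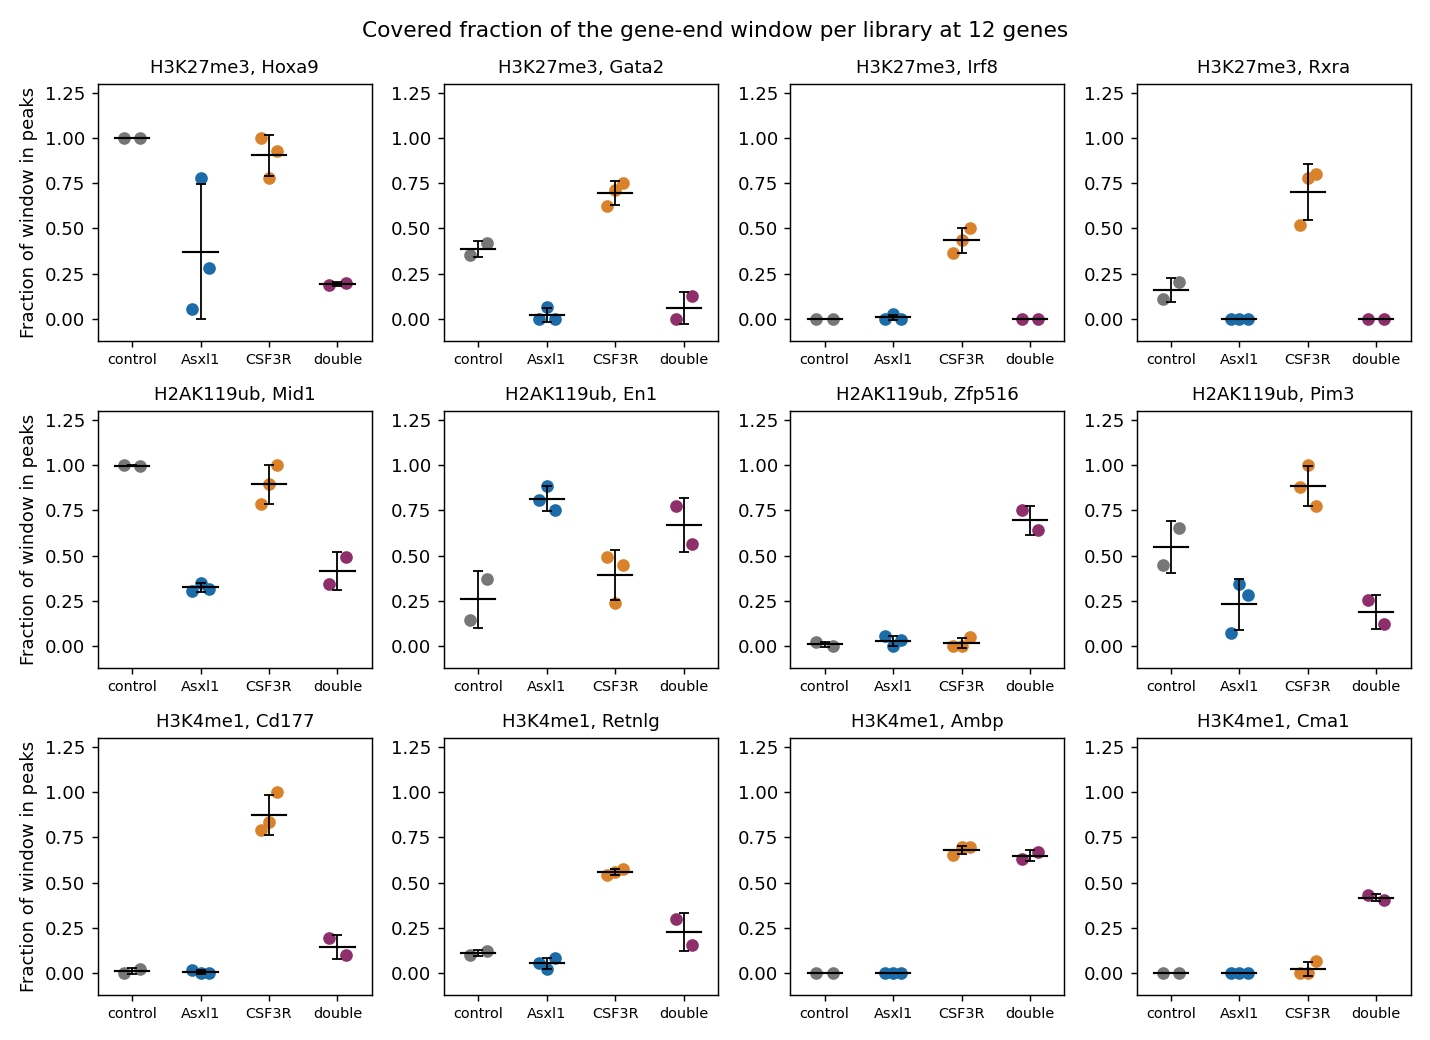
Fraction of the 10 kb window at the gene end covered by peaks in each library for 12 named genes, with H3K27me3, H2AK119ub and H3K4me1 in turn; dots are libraries, and lines and bars are mean ± SD by genotype. Cd177 is covered over 0.88 of its window by H3K4me1 with CSF3R and 0.15 in double cells, and Gata2 over 0.70 and 0.06 by H3K27me3, the latter call being lost without single libraries.

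The guide effect on H3K4me1 differed with CSF3R status at 36 gene ends, with 14 positive and 22 negative interactions. Cd177 had 0.01 ± 0.02 in control, 0.01 ± 0.01 with the guide, 0.88 ± 0.11 with CSF3R and 0.15 ± 0.07 in double cells (interaction -0.72, adjusted p = 0.00393). Cma1 had 0.00 ± 0.00, 0.00 ± 0.00, 0.02 ± 0.04 and 0.42 ± 0.02 (interaction 0.40, adjusted p = 0.0041). Irf1, an interferon response factor gene, and Mybl2, a cell cycle factor gene, both named after their values were seen, had 0.61 ± 0.03 and 0.70 ± 0.06 with CSF3R and 0.15 ± 0.08 and 0.14 ± 0.04 in double cells (adjusted p = 0.0029 for each). Mast cell genes (1 of 8 passed, 2 adjusted over the list alone; adjusted p = 0.00418) and lymphoid genes (0 of 4 passed, 1 adjusted over the list alone; adjusted p = 0.00796) were called higher, each with adjusted p = 0.986 with an estimated correlation. The mast cell call was lost without CSF3R replicate 3 (0.0502), double replicate 1 (0.533) or double replicate 2 (0.159), and the lymphoid call with a 2 kb window (0.0824); the lymphoid list had no test without double replicate 1. Counts of positive and negative interactions were 6 and 7 without either control library, 7 and 9 without Asxl1 replicate 1, 6 and 9 without Asxl1 replicate 3, 16 and 45 without CSF3R replicate 1, 2 and 17 without double replicate 1 and 4 and 9 without double replicate 2.

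H3K4me1 away from gene ends is a usual mark of enhancers. A region on chromosome 3 from 122348751 to 122349000, whose nearest gene end is that of Dnttip2, was covered in full in all 3 CSF3R libraries and in no other library, so it rose against control (adjusted p = 0.00111) and fell in double cells (adjusted p = 0.000256). A region near Eps8l3 (chromosome 3, 107856551 to 107856950) was covered in full with CSF3R, over 0.25 ± 0.35 in double cells and not in control or with the guide. Regions near Perp (chromosome 10, 18837101 to 18837500) and Traf3ip2 (chromosome 10, 39687651 to 39687950) were covered in full in both control libraries and in none of the other 8 libraries. The regions near Dnttip2, Eps8l3, Perp and Traf3ip2 are 250 to 400 bp long. Ranking by a covered fraction, which cannot exceed 1, favours such short regions. Regions near Ifi206, an interferon-inducible gene (chromosome 1, 173480551 to 173481800), and Dapk2, a death-associated kinase gene (chromosome 9, 66258551 to 66260000), rose from 0.00 ± 0.00 in control to 0.95 ± 0.06 and 0.90 ± 0.12 with the guide alone.

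In double cells, regions near Glrp1 (chromosome 1, 88562451 to 88562650) and within Bcl2, the survival gene (chromosome 1, 106610501 to 106610700), were covered in full in both double libraries and in none of the others. Both regions are 200 bp long, the shortest peak width in the data, so full coverage there means 1 peak of the least width. Regions called higher in double against CSF3R had a median length of 950 bp. A region within Fndc3b (chromosome 3, 27612401 to 27613550) fell from 0.99 ± 0.03 with CSF3R to 0.00 ± 0.00. Negative interactions were largest near Syk, an immune receptor kinase gene (0.39 ± 0.07, 0.63 ± 0.30, 0.91 ± 0.07 and 0.00 ± 0.00 in control, guide, CSF3R and double cells), and near Th (0.59 ± 0.17, 0.90 ± 0.12, 0.83 ± 0.06 and 0.03 ± 0.04), and positive ones near Ssr3 and Otos. Of 15995 regions, 26 rose and 147 fell with the guide alone, and 950 rose and 568 fell with CSF3R alone. Further, 904 rose and 748 fell in double against CSF3R and 1764 rose and 1397 fell in double against control. The interaction was positive at 578 and negative at 166. Of the 147 regions that fell with the guide alone 83 were covered in 2 libraries, and with regions seen in at least 3 libraries the guide gave 47 calls. Of the 904 regions that rose in double against CSF3R, 500 were covered in 2 libraries alone, both of them double, and of the 578 positive interactions 427 were covered in 2 libraries. With regions seen in at least 3 libraries the interaction count was 1, and 1 of the 744 calls was kept.

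Single libraries also moved the distal counts. Guide against control gave 12 and 168 without control replicate 1, 23 and 250 without control replicate 2, 162 and 120 without Asxl1 replicate 2 and 34 and 96 without Asxl1 replicate 3. CSF3R against control gave 424 and 407 without control replicate 1 and 432 and 461 without control replicate 2. Double against control gave 929 and 797 without control replicate 1 and 986 and 975 without control replicate 2 and 2845 and 752 without double replicate 2. Double against CSF3R gave 1920 and 472 without double replicate 2. The interaction gave 382 and 101 without Asxl1 replicate 3, 876 and 391 without double replicate 1 and 1693 and 246 without double replicate 2. The named regions near Perp, Traf3ip2, Dnttip2, Eps8l3, Ifi206, Dapk2, Glrp1, Bcl2 and Fndc3b kept their calls in every such fit, in which distal regions, unlike gene ends, were not filtered again. Without 1 of their libraries those near Perp, Traf3ip2, Glrp1 and Bcl2 thus rested on 1 covered library. Of the 4 interaction regions those near Ssr3 and Th kept theirs. With at least 3 libraries required, the regions near Perp, Traf3ip2, Glrp1 and Bcl2 were not tested, and the 4 interaction regions no longer passed (adjusted p = 0.0525 to 0.0689). Those near Ifi206 and Dapk2 had no test without peaks overlapping IgG peaks.

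**Figure D3:**
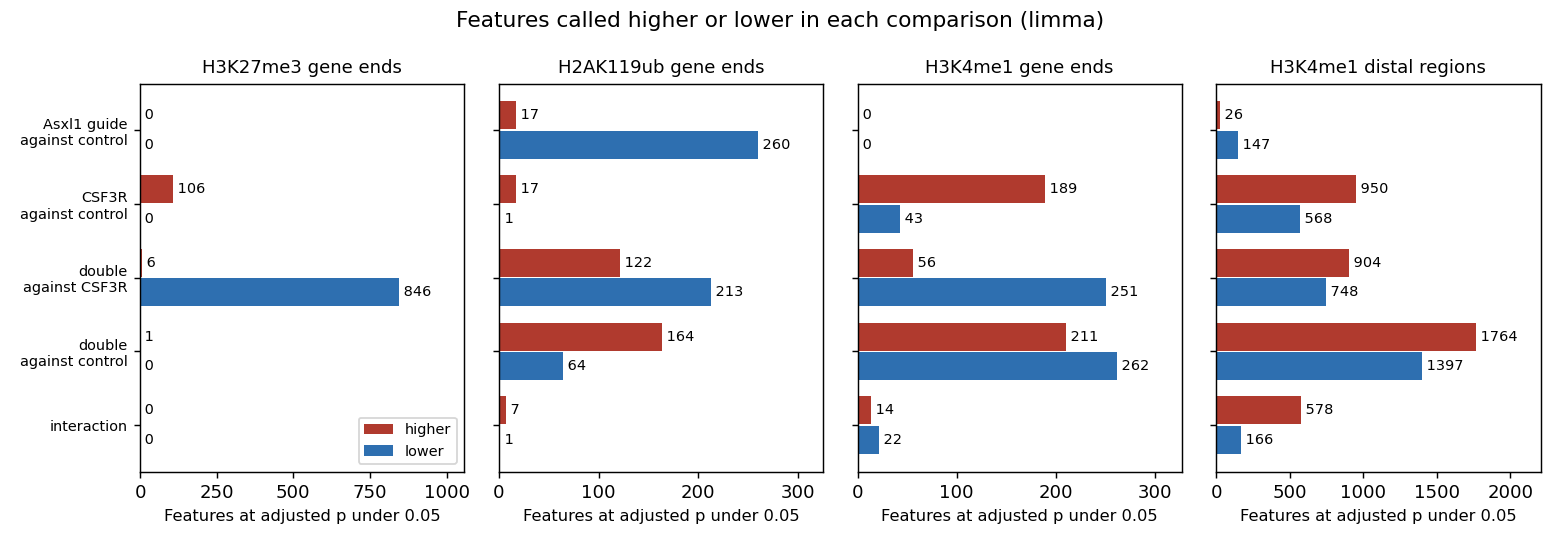
Number of gene ends or distal regions higher (red) and lower (blue) at an adjusted p under 0.05 in each comparison, by mark, with x axes that differ in scale between panels. H3K27me3 falls at 846 gene ends in double against CSF3R and H2AK119ub at 260 with the guide alone, counts that become 0 and 11 without some single libraries.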

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

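The tests of explanations in this part were chosen after the results they concern were seen, except the first test of a wrong label, which was written down before its value was known; the interaction tests were fixed beforehand.

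The effect of the Asxl1 guide differed with CSF3R status, by a test of the interaction itself, at 8 gene ends for H2AK119ub, 7 of them positive, and the count was 0 without either control library, any 1 Asxl1 library or double replicate 1. It differed at 36 gene ends for H3K4me1, with Cd177 at -0.72 and Cma1 at 0.40, and the count ran from 13 to 61 when 1 library was left out (13 without either control library or double replicate 2, 61 without CSF3R replicate 1). It differed at 744 distal H3K4me1 regions, 1 when a region had to be seen in at least 3 libraries, and at 483 without Asxl1 replicate 3 and 1939 without double replicate 2. The merged IgG list, which entered no comparison between genotypes, held 53972 peaks, more than the 45373 of the longest list of any mark.

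H3K27me3 peaks were narrower with the Asxl1 guide in both CSF3R backgrounds, by -0.87 in log2 mean width, and by -1.01 to -0.73 when 1 library was left out. A lower yield of peaks is argued against as the whole cause, since with covered length in the fit the effect was -0.73 (exact permutation p = 0.01, the smallest that 100 arrangements can give). Background at IgG positions is argued against too, since without peaks overlapping IgG peaks it was -0.78 (exact permutation p = 0.01, again the smallest possible). Sequencing depth and a peak-calling difference between the guide and other libraries stay open, because neither is known and covered length stands in for depth only in part. An effect of Asxl1 truncation on the spread of H3K27me3 may also be the cause and stays a hypothesis, as does any other difference between the guide and non-targeting cells.

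H3K27me3 was lower at 846 gene ends in double than in CSF3R cells, among them Hoxa9, Gata2, Irf8 and Cdkn2a. A lower yield of the double libraries as the whole cause is argued against, since without Asxl1 replicate 2 and with covered length in the fit the count was 564, and 484 of the 852 calls were kept. Yield as a large part of the cause stays open, because the count without that library was 2384 before covered length entered the fit, and because covered length was 35.9 Mb with CSF3R and 16.7 Mb in double cells and follows the comparison. No gene end passed in limma without CSF3R replicate 3, double replicate 1 or double replicate 2 (1078, 1204 and 798 at an unadjusted p under 0.05), so the calls rest on these libraries. A loss of H3K27me3 caused by Asxl1 truncation in CSF3R-mutant cells may account for the rest and was not tested apart from yield.

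Asxl1 H3K27me3 replicate 2 stood apart, with 53.0 Mb covered against 4.73 and 12.4 Mb in its group, and 32.5% of its length in gene-end windows. A CSF3R library under a wrong label was tested first at the 106 gene ends called higher in CSF3R than in control, where its median fraction was 0.10, against 0.50 to 0.58 in the CSF3R libraries and 0.03 and 0.08 in control, which argues against it. Because those gene ends had been chosen with the doubtful library in the variance, which favours a low value there, a second test took the 1137 chosen without it: its median was 0.345, between control (0.134 and 0.215) and CSF3R (0.465 to 0.525). Its mean peak width of 1168 bp, against 1797 to 2051 bp in the CSF3R libraries, argues against a CSF3R library of the same quality. Its Jaccard indices were 0.38 to 0.43 with CSF3R libraries (0.60 to 0.66 among themselves), 0.27 and 0.35 with control and 0.09 and 0.23 with its own group. They cannot decide, since unequal covered lengths limit this index. Of the other guide libraries 99.5% and 96.8% of the length lay inside it. For control this was 91.3% and 86.9%, and for the CSF3R libraries 67.8 to 74.0%. These shares also follow covered length, so a CSF3R library of another quality cannot be told apart from a deeper guide library. Background at IgG positions is argued against by the 2.55% of its length inside IgG peaks (2.36 to 4.93% in the other H3K27me3 libraries), and a biological difference within the group was not tested.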

How the results depend on the processing

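The whole-gene window, the joint use of the covered-length covariate and leaving out Asxl1 replicate 2, and all settings for mean peak width were chosen after seeing the data. Of 557 alternatives to counts, lists and effects of the comparisons, 347 kept the direction and the side of the threshold, or for a count stayed within 1.5 times, and of the 242 that did not leave out a library 144 did. Removing the shortest peaks of each library, a 2 kb distance for distal regions and the other overlap measures moved none of the results they were applied to past these bounds. For the 127 named values, 1525 of 2121 alternatives kept the call, 589 had the same direction but no longer passed, and 7 reversed; 24 of the values never lost their call where they were tested. Below, comparisons are guide, CSF3R and double each against control unless double against CSF3R is written, and the numbers are called features. Unless a reason is given, the cause was not tested.

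Any overlap in place of the fraction gave 63 (guide), 206 (CSF3R), 244 (double against CSF3R), 166 (double) and 227 (interaction) for H3K27me3, 184 (CSF3R), 486 (double) and 606 (interaction) for H2AK119ub, and 60 (guide) and 297 (interaction) for H3K4me1. Covered length as covariate gave 230, 487, 452 and 91 for H3K27me3 (guide, CSF3R, double, interaction) and 21, 28, 685, 396 and 0 for H2AK119ub (guide, CSF3R, double against CSF3R, double, interaction). With Asxl1 replicate 2 also left out, double gave 418 for H3K27me3. Complete separation of the groups, which uses no test, gave 100, 534 and 676 for H3K27me3 (guide, CSF3R, double), 754, 332, 673 and 1168 for H2AK119ub (guide, CSF3R, double against CSF3R, double), and 120, 379 and 825 for H3K4me1 (guide, CSF3R, double).

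The 2 kb window gave 186 (CSF3R) and 6 (double) for H3K27me3, 124 (guide) and 3 (interaction) for H2AK119ub, and 20 (guide), 189 (double against CSF3R), 294 (double) and 61 (interaction) for H3K4me1. With no filter on low coverage these were 330 (CSF3R), 7 (double) and 52 (interaction) for H3K27me3, 180 (guide), 52 (CSF3R), 375 (double) and 61 (interaction) for H2AK119ub, and 31 (guide) and 117 (interaction) for H3K4me1. The whole-gene window gave 0 (CSF3R), 285 (double against CSF3R) and 0 (double) for H3K27me3, 10 (CSF3R), 145 (double) and 1 (interaction) for H2AK119ub, 3 (guide) for H3K4me1, and 7 lists for H2AK119ub. Merged regions, which test other features than gene ends, gave 0, 563 and 0 for H3K27me3 (CSF3R, double against CSF3R, double), 302, 3834, 3947 and 2460 for H2AK119ub (the same and interaction), and 227, 2005, 2186, 4114 and 958 for H3K4me1 (guide, then the same 4).

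Without peaks overlapping IgG peaks H3K27me3 gave 561 (double against CSF3R) and 12 (interaction), H2AK119ub 110 (guide), 4 (CSF3R), 167 (double against CSF3R) and 122 (double), and H3K4me1 2 (guide) and 193 (double against CSF3R), with 5 lists for H3K27me3 and 2 for H2AK119ub. There H3K27me3 in double against CSF3R reversed to 0.055 at Kif1c, 0.084 at Hoxa9, 0.065 at Cdkn1c and 0.13 at Hoxb8, and H2AK119ub to 0.22 at Gata2 and 0.16 at Rara with the guide and -0.091 at Muc4 with CSF3R. Whole peaks were removed here, wide ones more often, so these reversals and the lost list calls do not show background at those gene ends. With regions seen in at least 3 libraries, distal counts were 47 (guide), 1007 (double against CSF3R) and 1 (interaction); regions covered in 2 libraries, 83, 500 and 427 of the 173, 1652 and 744 calls, are then not tested, and the cause of the other losses was not tested. Number of peaks in place of covered length gave guide effects of 0.13 for H3K27me3 (exact permutation p = 0.86) and 0.0084 for H2AK119ub (exact permutation p = 0.99). With an estimated correlation camera called 0, 0 and 0 lists for the 3 marks, against 8, 4 and 3 at the preset one.

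A block for replicate number gave 0, 102 and 0 for H3K27me3 (CSF3R, double against CSF3R, double), 114, 2, 41, 150 and 0 for H2AK119ub (guide, CSF3R, double against CSF3R, double, interaction), 3 (guide) and 13 (interaction) for H3K4me1, and 81 (guide) and 217 (interaction) for distal regions. It gave a CSF3R effect on H2AK119ub covered length of 0.69 (exact permutation p = 0.15) and a guide effect on H3K27me3 width of -0.87 (exact permutation p = 0.05), and the guide effect on H2AK119ub width had an exact permutation p of 0.18. Residuals of libraries with the same number had a median correlation of -0.01 for H3K27me3, 0.01 for H2AK119ub and 0.15 for H3K4me1, against 0.0048, -0.0040 and -0.15 for different numbers. H3K4me1 thus gave a hint of pairing, but its same-number correlations ran from -0.11 to 0.40, and the labels name no shared batch or day.

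Leaving out 1 library gave these ranges, in the order guide, CSF3R, double against CSF3R, double and interaction. Counts were 0 to 828, 0 to 1139, 0 to 2397, 0 to 289 and 0 to 0 for H3K27me3; 11 to 384, 0 to 81, 80 to 467, 58 to 280 and 0 to 56 for H2AK119ub. They were 0 to 1, 69 to 248, 62 to 348, 171 to 492 and 13 to 61 for H3K4me1, and 130 to 282, 831 to 1682, 1282 to 2392, 1726 to 3597 and 483 to 1939 for distal regions. Covered-length effects of guide and CSF3R were -1.21 to -0.34 and 0.14 to 1.01 for H3K27me3, -0.35 to 0.042 and 0.49 to 0.89 for H2AK119ub, and -0.33 to -0.06 and 0.01 to 0.28 for H3K4me1. The guide effect on H3K27me3 width was -1.01 to -0.73 and on H3K27me3 inside H2AK119ub 6.37 to 17.3 points. Lists called were 7 to 8, 0 to 5 and 0 to 5 for the 3 marks in the order of the report.

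Depth is unknown, so a difference in covered length between libraries limits every count. In simulated double against CSF3R data, shifts of 0.3 were recovered at 6% for H3K27me3, 54% for H2AK119ub and 67% for H3K4me1, and unchanged gene ends made up 1.22, 7.36 and 7.82% of the calls. The simulation left out shifts shared by a whole library, such as those of covered length. Its shares therefore do not give the rate of false calls in the real data.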

Other observations

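All tests in this part were chosen after the data were seen.

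Distal H3K4me1 regions near genes of the fixed lists were compared with all other distal regions. Near JAK-STAT target and cytokine signalling genes, 17 of 125 regions were higher in double than in CSF3R cells, 13.6% against 5.59% of other regions (exact Fisher p = 0.000664). These lay near Myc, Bcl2, Il2ra, a T-cell growth factor receptor gene, Bcl6, a transcriptional repressor gene, Il1r2, Il4ra, Osm, which encodes oncostatin M, and Pim3, among others. Near cell cycle inhibitors and D/E cyclins, 11 of 44 regions were lower in double cells than in control, 25% against 8.69% (exact Fisher p = 0.00112), near Cdk6, Ccnd2 and Gadd45a. Adjusted over 140 tests both exact Fisher results had p = 0.0782, so neither passed, and neighbouring regions are not independent.

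Gene ends with lower H3K27me3 in double than in CSF3R cells were compared with those of lower H2AK119ub. Of 2139 gene ends tested in both marks 506 were lower in H3K27me3 and 87 in H2AK119ub, and 64 were lower in both, against 20.6 by chance (exact Fisher, adjusted p = 1.73e-22). All 5 that were higher in H3K27me3 in that set, Mfsd6, Plxnc1, Itgb3, Zfp516 and Epha7, were also higher in H2AK119ub, against 0.147 by chance (exact Fisher, adjusted p = 1.7e-07). The coverage filter favours this overlap, since a gene end with little coverage elsewhere enters the set only through its double libraries. Zfp516 did so in both marks. This p therefore does not measure a shared rise. The hypothesis that the marks move together at part of the gene ends fits these 64, but gene ends are not independent and the H3K27me3 calls rest on single libraries.

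The guide effects without and with CSF3R T618I were correlated across features, to ask whether the guide shifts the same features in both backgrounds. For H2AK119ub r was 0.57 (exact permutation p = 0.01, one-sided, the smallest possible) and 0.62 with covered length regressed out (exact permutation p = 0.01). For distal H3K4me1 regions r was 0.19 (exact permutation p = 0.01) and 0.13 with covered length regressed out (exact permutation p = 0.04). For H3K27me3 r was 0.48 (exact permutation p = 0.03) and 0.31 with covered length regressed out (exact permutation p = 0.13). For H3K4me1 gene ends r was 0.27 (exact permutation p = 0.04) and 0.18 (exact permutation p = 0.12) in the same order. A shared guide effect in both backgrounds is thus a candidate explanation for H2AK119ub and, weakly, for distal H3K4me1. For H3K27me3 and H3K4me1 gene ends it cannot be told apart from covered length.

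The average effect of each genotype factor was set against 100 splits of the 10 libraries of a mark, the real split included, and the shares were not adjusted over the 8 results. For H2AK119ub the guide gave 585 calls, and 1 split gave as many (highest other 413). CSF3R T618I gave 441 calls for H3K4me1 gene ends, and 1 split gave as many (highest other 2), and 2257 for distal regions, again 1 split (highest other 17). In these 3 results no other split reached the real count, which argues against chance at the limit used here, fewer than 5 in 100. For H2AK119ub CSF3R T618I gave 149 calls and 4 splits gave as many, the highest being 585. The guide gave 13 calls for H3K4me1 gene ends with 2 splits as large (highest other 441), and 6 for distal regions with 3 splits as large (highest other 2257). These shares were under that limit too, but by a small margin and without adjustment, so chance is not excluded for these results. Their highest other split was the other genotype factor, a structure of the samples. For H3K27me3 the guide gave 650 calls with 3 splits as large (highest other 2979), and CSF3R T618I 13 calls with 4 splits as large (highest other 1800). These shares were again under that limit by a small margin and without adjustment, so chance is not excluded here either. The highest other splits call several times the real count and so point to a structure of the samples, which leaves open what these calls follow. The highest guide split set the 5 libraries with the shortest covered length apart, and the highest CSF3R split put Asxl1 replicate 2 with the CSF3R libraries.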
